A study of Mus musculus with 4 samples.

How the data were processed

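Total RNA from 4 mouse samples was measured on Affymetrix Mouse 430 2.0 expression arrays, 1 array per sample. Per the labels, 2 samples were granulocytic myeloid-derived suppressor cells (G-MDSC) and 2 were neutrophils, all from female C57BL/6 mice. G-MDSC were taken from the spleen 3.5 weeks after subcutaneous injection of EL4 lymphoma cells and were selected on microbeads for Ly6G. Neutrophils were washed from the peritoneum after 2 injections of 1.5 ml of 12% casein given 16 h apart, with collection 3 h after the last. They were depleted of F4/80-positive cells and then selected for Ly6G. Red blood cells were lysed, and labelled cRNA was made from 100 ng of total RNA. The labels do not say whether the 2 samples of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

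The deposited values are signal intensities on a linear scale, made with GCOS 1.4 and MAS5 per the submitters' processing notes. The intensity values deposited by the authors have a mean of 500 in each of the 4 arrays when 2% of probe sets are trimmed at each end, so the arrays were already scaled to one another. Detection calls were not used here. Arrays have no read depth, and their number, 2 per group, limits the precision. The table holds 45101 probe sets, of which 64 are controls. In the platform annotation used here, 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none, and the single symbols name 18193 genes. Of these probe sets, 34741 were matched by gene ID to the RefSeq table of assembly GRCm38.p6, used for names alone, and 0 symbols needed updating. Probe sets with several symbols were not named, so the sort markers Ly6g, Ly6c1 and Ly6c2 are not reported here.

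The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Signals were used as log2(signal + 16), and folds are on that scale, which understates changes of dim genes. A probe set was kept if its signal was above the 40th percentile of its array in at least 2 of 4 arrays, which left 28754 probe sets. Each gene was represented by its kept probe set with the highest mean, giving 13139 genes. Differences are G-MDSC minus neutrophils, fitted with limma's lmFit and eBayes with an intensity trend. Tests were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot give a p below 0.33, so none was used.

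Gene lists for 34 programmes and cell types were fixed in advance, and 833 of their 920 entries had a probe set with 1 symbol. Several follow themes known from the study, so they are not independent evidence for those themes. Lists with at least 5 tested genes entered limma's camera with a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Camera sets a list against all other genes, while fry asks whether its genes move, on balance, one way.

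The rule for named genes was fixed at the same time. It took the 12 largest differences per direction among genes past the threshold whose arrays separated the groups and whose higher group lay above the median gene. It also took up to 2 called members per direction of each list, or its 2 brightest members where none was called, and a fixed set of markers. Members of lists that are only summarised are left out. Where both arrays of a group were at or below their own 40th percentile, the fold is given as a bound, a choice made after seeing the data. The bound sets the bright group's mean log2 value against the mean, per array, of the higher of that percentile and the signal itself. Bounds are also given, likewise chosen after seeing the data, with the highest of the 4 arrays' percentiles as a common floor and, where they moved by over 1.5 times, with 1 array left out.

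The functions were tested on simulated data for 13139 genes of this comparison, with 200 genes changed. At 8-fold, 72.7% of changed genes were recovered, at 4-fold 26.9% and at 2-fold 0%, with 5 unchanged genes called. With 1 of 34 lists moved 2-fold, that list was called and 0 others were. The simulated genes were independent, without array effects, whereas the estimated correlation within the measured cell cycle list was 0.666. The simulation therefore does not show how often camera calls lists of correlated genes wrongly. In the data 2149 genes were called, so the Benjamini-Hochberg cut-off was less strict than with 200 changed genes. The recovered shares are therefore not those of the measured comparison.

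The alternatives chosen before the data were examined were other pseudocounts (1 and 64), other filters, quantile and median normalization, other variance models, other choices of probe set, the replicate number as a block, and leaving out each array. After seeing the data, a floor for low signals and quantile normalization together with the block were added, as were list counts without neutrophils replicate 2. The spike-in controls added before labelling split the arrays by replicate number: their geometric mean signal was 6.7 and 11.3 in the replicate 1 arrays of G-MDSC and neutrophils, and 1639.4 and 2204.1 in the replicate 2 arrays. The replicate number was therefore treated as a technical batch that holds both groups, and blocked and within-number values are given. Bootstrap intervals in the closing section cover 95% and come from 10000 draws of genes, which are not independent replicates. The permutation test there shuffled genes between lists 100000 times, leaving out genes held by more than 1 of the lists.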

Results

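Gene expression was measured in 2 samples of G-MDSC and 2 of neutrophils. G-MDSC are immature granulocytic cells that accumulate in tumour-bearing mice and restrain T cells. The neutrophils were drawn into the peritoneum by casein, a milk protein used to provoke inflammation. The comparison asks how the 2 kinds of granulocyte differ in gene expression. In every array, cell kind went together with tissue, treatment of the mice and sorting steps. G-MDSC came from spleen after tumour injection, and neutrophils from the peritoneum after casein. The differences below therefore cannot be assigned to cell kind rather than to tissue, tumour, casein or sorting. The median signal per array was 75.8 and 80.7 in G-MDSC and 83.3 and 177.9 in neutrophils. Neutrophils replicate 2 stood apart at the low end, with a 40th percentile of 132.7 against 45.7 to 52.6 in the other 3 arrays. Its hybridization controls were the brightest (geometric mean 8074.2 against 3589.7 to 4989.2) and its 18S signal the lowest (3342.1 against 6395.7 to 10270.5). The 3' to 5' signal ratio of its actin controls was the highest, at 1.28, but that of its Gapdh controls the lowest, at 0.87. Across kept probe sets, which are not independent replicates, Pearson's r between replicates was 0.953 in G-MDSC and 0.875 in neutrophils. Between groups it ran from 0.766 to 0.885.

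G-MDSC and neutrophils differed widely. Of the 12 largest rises in G-MDSC, 6 were of primary or secondary granule proteins, and arginase 1 and several chemokines and cytokines were among the 12 largest falls. By limma, 1091 of 13139 genes were higher and 1058 lower in G-MDSC, of which 1079 and 1054 differed at least 2-fold. At an unadjusted p under 0.05 there were 3890 genes. All 2149 called genes remained called with the replicate block, which called 1699 higher and 1607 lower. The arrays of the groups were separate for 59.5% of genes, where chance gives 33.3%. The median gene was 0.18 lower in G-MDSC on the log2 scale, and list medians below are given relative to it unless said to be as measured. As measured, the median gene was at 0 in the replicate 1 pair and -0.33 in the replicate 2 pair. The counts rest on moderation across genes: without it limma called 0 genes, with 2379 at an unadjusted p under 0.05, and without the intensity trend it called 148 higher and 331 lower. A floor for low signals in place of the pseudocount left 0 as well, with 3230 at an unadjusted p under 0.05. Without G-MDSC replicate 1 there were 429 higher and 574 lower, and without G-MDSC replicate 2 there were 511 and 561. Without neutrophils replicate 1 there were 2419 and 3472, and without neutrophils replicate 2 there were 1707 and 1456.

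The largest rises in G-MDSC were Mpo, the myeloperoxidase of azurophil granules, and Camp, the cathelicidin of specific granules. The log2 difference of Mpo was 5.12 ± 0.39 (SE, n = 2 per group; limma adjusted p = 1.7e-05), with signals of 8580 and 3980 in G-MDSC against 150 and 157 in neutrophils. Camp was higher by 5.10 ± 0.37. The serine proteases Elane, Ctsg and Prtn3 were higher by 4.74 ± 0.44, 4.53 ± 0.51 and 4.16 ± 0.47, and Ltf, lactoferrin, by 4.38 ± 0.44. Transcripts of antibody-secreting cells were also among them, with Jchain higher by 4.49 ± 0.39 and Igha by 4.0 ± 0.34, or 6.15 with the median of probe sets. Reck, an inhibitor of metalloproteinases, was higher by 4.21 ± 0.37, Fosb, an AP-1 subunit, by 3.98 ± 0.30 and Gm19696 by 4.0 ± 0.74, or 2.46 without neutrophils replicate 2. Prom1 was at least 16.4-fold higher, since both neutrophil arrays were below their 40th percentile. This bound was 11-fold with the highest of the 4 arrays' percentiles as a common floor, and 10.6-fold and 25.3-fold without G-MDSC replicates 1 and 2.

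Arg1, the enzyme that breaks down arginine, showed the largest fall. Its signal was 28.2 and 6.62 in G-MDSC, below the 40th percentile of both arrays, against 18980 and 40390 in neutrophils, so it was at least 426-fold lower in G-MDSC (limma adjusted p = 1.3e-06). By the same bound Serpinb2 was at least 232-fold lower, and the chemokines Ccl12, Ccl22 and Ccl24 were at least 119-fold, 65.3-fold and 44.8-fold lower. Csf3, the granulocyte growth factor, was at least 84.1-fold lower and Cma1, a mast cell chymase, at least 41.3-fold lower. With the common floor the bounds were lower, at 186-fold for Arg1, 102-fold for Serpinb2, 52-fold for Ccl12, 28.6-fold for Ccl22, 19.6-fold for Ccl24, 36.8-fold for Csf3 and 18.1-fold for Cma1. Leaving out neutrophils replicate 1 or 2 gave 450-fold or 120-fold for Serpinb2, 210-fold or 67.3-fold for Ccl12, 34.8-fold or 123-fold for Ccl22, 70.5-fold or 28.5-fold for Ccl24 and 24.1-fold or 70.8-fold for Cma1. Dab2 differed by -6.75 ± 0.39 (SE, n = 2 per group), Ccl7 by -6.49 ± 0.38, Cxcl1 by -6.40 ± 0.43, Il1a by -6.33 ± 0.68 and Pf4, a platelet chemokine, by -6.31 ± 0.46. Macrophage and mast cell markers were lower in the same arrays, as given below, so other cells among the neutrophils may share in these falls. Which cells carried these transcripts, Arg1 included, was not tested.

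**Figure D1:**
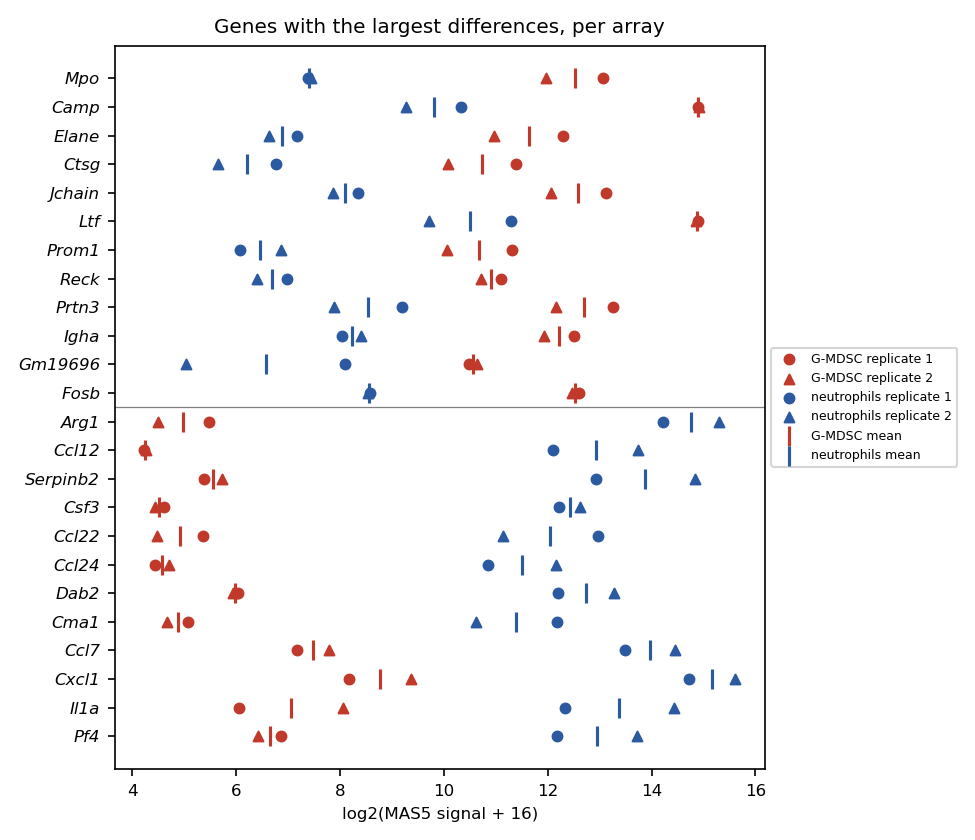
The 12 genes with the largest rise in G-MDSC (top) and the 12 with the largest fall (bottom), as log2(MAS5 signal + 16) on the horizontal axis. Each point is 1 array (red G-MDSC, blue neutrophils; circle replicate 1, triangle replicate 2) and each tick is a group mean; both arrays of 1 group lie above both of the other for each gene.

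Markers chosen in advance showed a mixed picture. Adgre1, the F4/80 antigen against which the neutrophils had been depleted, was lower in G-MDSC, by -2.99 ± 0.33 (SE, n = 2 per group). Cd244a, which encodes 2B4, was higher by 1.60 ± 0.30, and Tnf was lower, by -4.77 ± 0.44. The log2 differences of Itgam (-0.08 ± 0.31), Csf1r (-0.58 ± 0.29), Cybb (0.16 ± 0.30), Il1b (-0.52 ± 0.35), S100a8 (-0.31 ± 0.34), S100a9 (-0.45 ± 0.34) and Lamp2 (-0.39 ± 0.30) did not pass limma's threshold. Nos2, the inducible nitric oxide synthase, was dim in both neutrophil arrays (16.9 and 14.3, against 80.2 and 113 in G-MDSC), so it was at least 1.11-fold higher in G-MDSC, with no bound left under the common floor, without neutrophils replicate 1 or without G-MDSC replicate 2. It was not called (limma adjusted p = 0.265), except with quantile normalization and the replicate block together (adjusted p = 0.0151). The sign of Itgam turned with median scaling and that of Lamp2 with the median of probe sets, and S100a9 was at 0 with quantile normalization. Without neutrophils replicate 1, Itgam was at 0.18, and Il1b was at -0.87 and passed the threshold (adjusted p = 0.0236).

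Granule genes rose as groups. Of 9 azurophil granule genes tested, 6 were higher and 1, Ctsc (log2 difference -1.84 ± 0.33), was lower in G-MDSC, with the same counts adjusted over the list alone. The list median lay 3.66 above that of all genes (camera adjusted p = 3.4e-05; adjusted p = 0.447 with an estimated correlation). Of 18 specific and gelatinase granule genes, 8 were higher, or 13 adjusted over the list alone and with the replicate block, and 0 lower (median 1.14 above all genes; camera adjusted p = 2.4e-08; adjusted p = 0.403 with an estimated correlation). Of 15 granulocyte precursor genes, 4 were higher, or 5 adjusted over the list alone, among them Fcnb, a ficolin, by 3.22 ± 0.41. The number was 2 with quantile normalization. The precursor list missed the threshold (camera adjusted p = 0.0859) and passed it with the replicate block (adjusted p = 0.0254) and with no filter (0.0226). Without G-MDSC replicate 2 and without neutrophils replicate 1 it passed as well, with medians as measured of 0.47 and 0.86. The blocked fit and these fits rest on the spread pooled over genes, so their passes add no strength.

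Cell cycle and autophagy genes were higher in G-MDSC. Of 43 cell cycle genes, 16 were higher, or 17 adjusted over the list alone, and 0 lower. Ube2c, which drives exit from mitosis, was higher by 2.68 ± 0.45 (SE, n = 2 per group), and Tk1, a thymidine kinase, was at least 2.90-fold higher (1.95-fold with the common floor), a call lost without either G-MDSC array (adjusted p = 0.579 without replicate 1 and 0.264 without replicate 2). The list median was 1.42 above all genes (camera adjusted p = 1.8e-09; adjusted p = 0.584 with an estimated correlation). As measured, it was 1.24 over all arrays, 1.82 in the replicate 1 pair and 0.61 in the replicate 2 pair. The number of higher members was 26 without neutrophils replicate 2. Of 29 autophagy genes, 9 were higher, or 11 adjusted over the list alone and 14 with the replicate block, and 0 lower, with Ulk1, the initiating kinase, higher by 2.14 ± 0.32 (median 0.84 above all genes; camera adjusted p = 8.2e-06; adjusted p = 0.447 with an estimated correlation).

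Inflammatory genes were lower in G-MDSC. Of 36 cytokine and chemokine genes, 26 were lower and 0 higher, or 29 and 2 adjusted over the list alone and 27 and 2 without neutrophils replicate 2, with a median of -2.86 relative to all genes (camera adjusted p = 1.9e-17; adjusted p = 0.447 with an estimated correlation). Of 35 NF-kappaB pathway and target genes, 21 were lower and 0 higher, with the same counts adjusted over the list alone. Icam1, an adhesion molecule, differed by -4.59 ± 0.37 and Ikbke, a kinase of the pathway, by -4.19 ± 0.42 (relative median -1.08; camera adjusted p = 9.8e-11; adjusted p = 0.45 with an estimated correlation). Of 25 Fc, complement and scavenger receptor genes, 10 were lower and 0 higher, or 10 and 2 adjusted over the list alone and with the replicate block, with the scavenger receptors Msr1 and Marco at -5.89 ± 0.33 and -5.36 ± 0.46 (relative median -0.11; camera adjusted p = 0.000264; adjusted p = 0.403 with an estimated correlation). The median of this receptor list lay near that of all genes, so its call rests on a part of its members. Marco is also 1 of the macrophage markers. Macrophage and mast cell markers were lower in the same arrays, as given next.

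Markers of other cell types moved with the groups. Of 24 macrophage markers, 11 were lower and 1, Vcam1 (3.58 ± 0.67), was higher in G-MDSC, with the same counts adjusted over the list alone. These were 11 and 3 without neutrophils replicate 2 and 12 and 2 with the replicate block. The Vcam1 call was lost with the median of its 3 probe sets (2.03, adjusted p = 0.0694), which ran from 0.07 to 3.58, and its difference was 2.35 without neutrophils replicate 1. The transcription factor Maf differed by -3.74 ± 0.31 (relative median -1.20; camera adjusted p = 3.2e-05; adjusted p = 0.584 with an estimated correlation). Of 17 mast cell and basophil markers, 7 were lower and 1 higher, or 9 and 2 adjusted over the list alone and with the replicate block. Mcpt4, a mast cell protease, was at least 18-fold lower (7.89-fold with the common floor). The basophil protease Mcpt8 was at least 6.73-fold higher, a call lost without G-MDSC replicate 1 (adjusted p = 0.237). That bound was 4.53-fold with the common floor and also without neutrophils replicate 1, and 3.75-fold and 12.1-fold without G-MDSC replicates 1 and 2. The mast cell list had a relative median of -1.52 (camera adjusted p = 0.000335, and 0.403 with an estimated correlation). As measured, its median was -1.71, or -0.54 with the floor for low signals, so much of its size rested on dim signals. The macrophage and platelet medians shrank too, from -1.39 to -0.85 and from -0.94 to -0.26. Those of the monocyte and dendritic cell lists held, at -0.93 and -1.2 with the floor. The mast cell and macrophage lists still passed with it (camera adjusted p = 0.0072 and 0.00137). Of 14 monocyte markers, 4 were lower, or 8 lower and 1 higher adjusted over the list alone, with Ms4a6c at -3.12 ± 0.35 (-1.80 with the median of probe sets) and Ms4a6b at -3.04 ± 0.32 (camera adjusted p = 0.00101; adjusted p = 0.403 with an estimated correlation). The number was 7 without neutrophils replicate 2 and 10 with the replicate block. Of 17 dendritic cell and antigen presentation markers, 9 were lower on both bases, or 4 with median scaling, including Cd209a at -2.80 ± 0.53 (camera adjusted p = 3.2e-05; adjusted p = 0.403 with an estimated correlation). Of 15 platelet and megakaryocyte markers, 3 were lower on both bases, among them Thbs1, thrombospondin 1, at -6.00 ± 0.31 (camera adjusted p = 0.0374; adjusted p = 0.577 with an estimated correlation). That list's call was lost under quantile normalization (adjusted p = 0.0692), the filter at the 60th percentile (0.0656), the median of probe sets (0.103) and the floor (0.265).

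The remaining cell type lists did not pass the test. Of 10 NK cell markers 2 were lower (camera adjusted p = 0.0566), and of 16 T cell markers 2 were lower (0.131). With the floor, their medians as measured moved from -1.12 to -0.54 and from -0.71 to -0.24. Without neutrophils replicate 2 the NK cell list passed the threshold (adjusted p = 0.0189), with 4 lower. It also passed with median scaling (0.0181, with 1 lower), with no filter (0.0171) and with the median of probe sets (0.0435), and had 0 lower with quantile normalization. Of 17 B cell markers 2 were higher and 1 lower (0.404), or 1 higher and 0 lower with median scaling. Of 14 erythroid markers 1 was higher (0.988), of 6 eosinophil markers 1 was lower (0.898) and of 8 mesothelial and stromal markers 0 were called (0.203). Adjusted over the list alone, the erythroid list had 0 higher and the eosinophil list 1 higher and 1 lower. The NK, T and B cell counts were the same. Without neutrophils replicate 2, 3 erythroid markers were higher and 1 lower, and 2 eosinophil markers were higher and 1 lower.

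Ribosome biogenesis genes were lower in G-MDSC. Of 32 tested, 20 were lower, or 28 adjusted over the list alone, and 0 higher, with 13 lower under median scaling and the nucleolar proteins Nop16 and Gar1 at -2.71 ± 0.41 and -2.68 ± 0.39 (relative median -1.21; camera adjusted p = 1.7e-11; adjusted p = 0.403 with an estimated correlation). Of 28 unfolded protein response genes, 10 were lower and 4 higher, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.0859). With median scaling 5 were lower and 4 higher, while the list passed the threshold with quantile normalization (adjusted p = 0.00973) and with the filter at the 60th percentile (0.0475). Asns, asparagine synthetase, was higher by 1.94 ± 0.33 and the chaperone genes Sdf2l1 and Pdia6 differed by -2.12 ± 0.35 and -2.11 ± 0.33. Of 36 lysosomal genes, 8 were lower and 2 higher, or 9 and 3 adjusted over the list alone (0.131). The acid phosphatases Acp5 and Acp2 differed by -2.59 ± 0.33 and -2.24 ± 0.35. Without neutrophils replicate 2 the lysosomal list passed the threshold (adjusted p = 0.0141), as it did with quantile normalization (0.0376), but with median scaling 2 genes were lower and 0 higher.

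Lists on reactive oxygen and suppressor cell genes had called members on balance lower in G-MDSC. Of 20 NADPH oxidase and antioxidant genes, 4 were lower, or 5 adjusted over the list alone, and 0 higher. The cystine transporter Slc7a11 differed by -4.80 ± 0.32 and Sod2, mitochondrial superoxide dismutase, by -4.08 ± 0.32. The list median lay 0.11 above that of all genes. As measured it was -0.07, and above 0 with quantile normalization (0.14) and median scaling (0.17). This list missed the threshold (camera adjusted p = 0.0999) and passed it with the replicate block (adjusted p = 0.00896). It passed too without G-MDSC replicate 1, without G-MDSC replicate 2 and without neutrophils replicate 2. Its medians as measured were then -0.03, -0.18 and -0.09. The blocked fit and these fits rest on the spread pooled over genes, so the passes add no strength. Of 28 genes linked to myeloid suppressor cells, 9 were lower and 3 higher, or 11 and 5 adjusted over the list alone, with Il10 at -3.72 ± 0.40. These were 11 and 5 without neutrophils replicate 2 and with the replicate block. It also missed the threshold (camera adjusted p = 0.0859) and passed it with the replicate block (adjusted p = 0.000152) and with the filter at the 60th percentile (0.0133). As measured, the median of the suppressor cell list was -0.19 and -0.52 without G-MDSC replicates 1 and 2. It was -0.59 and -0.16 without neutrophils replicates 1 and 2. The list passed the threshold in each of these fits, but they rest on the spread pooled over genes, so the passes add no strength.

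Of 32 genes of innate receptors and adaptors, 9 were lower and 3 higher, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.113; 0.0187 without G-MDSC replicate 2 and 0.0109 without neutrophils replicate 2). With median scaling 5 were lower and 2 higher, while the list passed with quantile normalization (adjusted p = 0.0452). C3ar1 differed by -3.96 ± 0.39, while Tlr1 was higher by 1.73 ± 0.31. Of 28 chemokine receptor and adhesion genes, 7 were lower and 4 higher, or 8 and 6 over the list alone (0.433; 0.0259 without neutrophils replicate 2), or 4 and 2 with median scaling. Itga4, an integrin, was higher by 1.77 ± 0.30, a call lost with the median of its 5 probe sets taken in each array (0.21, adjusted p = 0.762). Single probe sets ran from 0.22 to 1.77. Of 35 CREB and cyclic AMP signalling genes, 5 were lower and 3 higher on both bases (0.952), with Nr4a3 at -3.86 ± 0.44. In 4 lists, those of chemokine receptor, CREB, NADPH oxidase and erythroid genes, the median lay above that of all genes while camera pointed to neutrophils. Of 19 hypoxia response genes 4 were lower and 1 higher, or 5 and 1 over the list alone (0.0975; 0.0263 without neutrophils replicate 2 and 0.022 with quantile normalization). Egln3, an oxygen-sensing hydroxylase, differed by -1.99 ± 0.30. Of 26 apoptosis genes 5 were lower and 3 higher on both bases (0.475; 0.0497 without neutrophils replicate 2, with 8 lower, and 3 lower with median scaling), with Fas at -2.45 ± 0.37. Of 20 glycolysis genes 2 were lower and 2 higher, or 4 and 2 over the list alone (0.394; 7 lower without neutrophils replicate 2, 4 with quantile normalization, 1 with median scaling), with Pfkfb4 higher by 2.68 ± 0.34. Of 40 oxidative phosphorylation genes 3 were lower and 1 higher on both bases (0.294; 1 and 0 with median scaling), and of 12 haem biosynthesis genes 2 were higher on both bases (0.223; 4 without neutrophils replicate 2, 1 with quantile normalization). Of 24 mature neutrophil genes 2 were lower and 1 higher, or 1 and 1 over the list alone (0.297; 4 higher without neutrophils replicate 2). With median scaling 0 were called, and with quantile normalization 5 were higher and the list passed (adjusted p = 0.038). In these lists, the counts that the replicate block moved by over 1.5 times were 6 higher and 4 lower for mature neutrophil, 5 lower for glycolysis, 6 lower for oxidative phosphorylation and 7 higher for chemokine receptor genes.

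Interferon-stimulated genes differed between the replicate numbers. The median of 36 tested genes, as measured, was -1.46 in the replicate 1 pair, 0.60 in the replicate 2 pair and -0.47 over all arrays. Across all arrays 3 were lower, or 2 adjusted over the list alone, and 0 higher, with Cxcl10 at -4.04 ± 0.46 and Bst2 at -2.11 ± 0.38. The list missed the threshold (camera adjusted p = 0.0975, or 0.813 with an estimated correlation, and fry adjusted p = 0.656). It passed with quantile normalization (camera adjusted p = 0.022) and with the replicate block (0.024, with 10 lower and 1 higher). The block assumes 1 group difference in both replicate numbers, against the pair medians here, so that pass adds no strength. Without neutrophils replicate 2, 22 were lower and the list was called (adjusted p = 5.3e-08), as it was without G-MDSC replicate 2 (adjusted p = 2.1e-07). The median turned to 0.18 without G-MDSC replicate 1 (adjusted p = 0.56) and to 0.06 without neutrophils replicate 1 (adjusted p = 0.752).

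**Figure D2:**
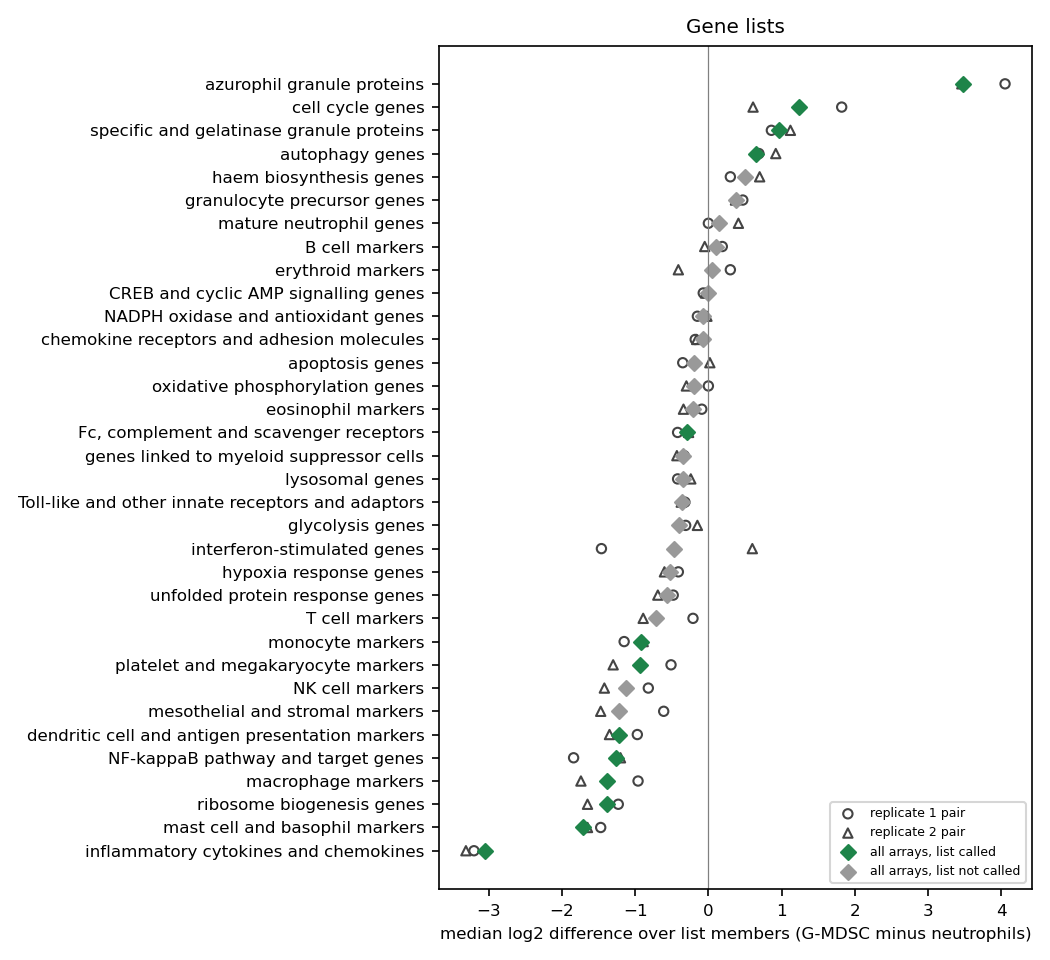
Median log2 difference as measured (G-MDSC minus neutrophils) over the tested members of each gene list. Diamonds are all arrays (green where camera's adjusted p is under 0.05), open circles the replicate 1 pair and open triangles the replicate 2 pair; interferon-stimulated genes lie at -1.46 in one pair and 0.60 in the other.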

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

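All tests of explanations in this part were chosen after the results were seen, and list medians are as measured. The spike-in control probe sets, which no comparison uses, gave a geometric mean signal of 1639.4 in G-MDSC replicate 2 and 2204.1 in neutrophils replicate 2, against 6.7 and 11.3 in the replicate 1 arrays. They were singled out because a signal appears outside the main measurement.

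Macrophage and mast cell genes were higher in the neutrophil arrays. A lower share of granulocytes there would raise all other markers alike only if both preparations held the same other cells. This is not known. Over 11 lists of other cell types the differences moved apart (permutation p of Kruskal-Wallis H = 0.00028). The same permutation test on the 9 without B cell and erythroid markers, with medians from -1.71 to -0.34, gave permutation p = 0.69. Spleen cells among the G-MDSC could raise those 2 lists, and the shuffling takes genes as independent, so neither result decides it. Some of the 9 list medians also rested on low signals, which were raised in neutrophils replicate 2. With the floor the T cell, mesothelial and platelet medians were -0.24, -0.25 and -0.26. The dendritic cell and monocyte medians held, at -1.2 and -0.93. The permutation test was not repeated with the floor. The mature neutrophil list, which a lower share of granulocytes would lower in the neutrophil arrays, had a median of 0.15 and missed the threshold (camera adjusted p = 0.297). S100a8 and S100a9, at -0.31 and -0.45, leaned the other way and were not called. A lower share therefore stays open. Macrophages or mast cells themselves may be a source: 11 of 24 macrophage and 7 of 17 mast cell markers were higher in neutrophils, too few to settle it, although F4/80 depletion should remove macrophages and Ly6G selection both. Adgre1, which encodes the F4/80 antigen itself, was higher in the depleted neutrophils, with signals of 4847 and 7136 against 817 and 643 in G-MDSC. The brightest macrophage marker, Csf1r, had signals of 16080 and 17390 in neutrophils and 11010 and 11270 in G-MDSC. The brightest mast cell marker, Hdc, named after its values were seen, had 24350 and 24020 in neutrophils. Neither Csf1r nor Hdc was called. Of the tested genes 8 and 3 stand in other lists, 21 and 9 exceeded the 40th percentile in both G-MDSC arrays, and expression by the neutrophils themselves stays open.

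Cell cycle and azurophil granule genes were higher in G-MDSC. Dividing erythroid or B cells from spleen would raise their own markers: the median of 31 such genes was 0.10 (interval -0.26 to 0.30) against 1.24 for the cell cycle list, yet it lay 1.26 above that of the 9 other lists (interval 0.79 to 1.51). Some of those 9 medians rested on the low signals raised in neutrophils replicate 2, and this contrast was not repeated with the floor. With that and a lower share of granulocytes among the neutrophils open, the contrast does not decide it for the cell cycle genes. Ly6G selection should, however, remove erythroid, B and plasma cells. The azurophil granule genes, which encode proteins of granulocyte granules, were not part of this test. Within G-MDSC, the median of replicate 2 minus replicate 1 was -1.13 for the cell cycle and -1.11 for the azurophil granule list. It was -0.01 for the B cell and 0.01 for the erythroid list. With 1 array on each side, these values leave the question undecided. Plasma cells stay open too, because Jchain and Igha were higher in G-MDSC. Immature granulocytes are a candidate explanation, but the granulocyte precursor list missed the threshold without the replicate block (camera adjusted p = 0.0859), passed it with the block (0.0254) and ran from 0.00791 to 0.45 over the alternatives, an estimated correlation included, so the tables do not decide it.

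Interferon-stimulated genes ran opposite ways in the replicate numbers. A labelling batch shared by both groups would move them one way, but the median of replicate 2 minus replicate 1 was 1.03 in G-MDSC (interval 0.76 to 1.45) and -0.85 in neutrophils (interval -1.07 to -0.70). The raised low signals of neutrophils replicate 2 are not the whole cause either, since quantile normalization left medians of -1.49 (interval -1.83 to -1.18) and 0.48 (interval 0.13 to 0.91). No biological explanation was tested, because no label separates the replicates.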

How the results depend on the processing

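The floor for low signals and quantile normalization together with the replicate block were chosen after the data were seen. Counts of called genes stayed within 1.5 times of those reported with pseudocounts of 1 and 64, both other filters, quantile normalization, median scaling and the 3 other choices of probe set, from 883 to 1154 higher and from 731 to 1238 lower. Quantile normalization kept 1713 of the 2149 called genes and median scaling 1668, with 0 changes of sign. The median over probe sets kept 1666 and turned the sign of 22. Without _x_at and _s_at probe sets, 1995 of the 2111 called genes still tested were kept and 7 turned sign. Without the intensity trend limma called 148 genes higher and 331 lower, all at least 2-fold. Without moderation it called 0 in each direction, with 2379 at an unadjusted p under 0.05. The floor also left 0 in each direction, with 3230 at an unadjusted p under 0.05, since it gave 811 genes no spread at all and lowered the prior degrees of freedom from 9.18 to 0.93. With the replicate block 1699 genes were higher and 1607 lower, and all 2149 remained called; with quantile normalization as well 1740 were higher. The numbers are not stated to pair the samples: the replicate differences of the 2 groups correlated at 0.24 across genes. The block added 4 lists to the 13 and ended none.

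Leaving out 1 array gave from 429 to 2419 genes higher and from 561 to 3472 lower, from 429 to 1839 at least 2-fold higher and from 561 to 3140 at least 2-fold lower. The lone array is then assumed to vary like the other group, and these fits, like the blocked one, have 1 residual degree of freedom and rest on the spread pooled over genes. The number of lists called ran from 15 to 22. Of the 96 genes followed across the alternatives, 17 lost their call without a G-MDSC array. Camera with an estimated correlation called 0 lists and fry 5, while quantile normalization with the block called 22. Fry called the dendritic cell, Fc receptor, mast cell and monocyte lists, and the hypoxia list that camera had not called (fry adjusted p = 0.041 each). It called none of the granule, cell cycle, autophagy, cytokine, NF-kappaB, ribosome biogenesis, macrophage and platelet lists (fry adjusted p from 0.0504 to 0.211). Camera with an estimated correlation has only 2 arrays per group to estimate it from. Replicate agreement was 0.882 in neutrophils and 0.96 in G-MDSC over all probe sets, and 0.85 and 0.935 with a pseudocount of 1; the cause of other changes was not tested.

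Among the lists and the named genes, signs turned only for those not called in the main fit. With median scaling the list medians, as measured, were 0.04 for apoptosis, 0.15 for chemokine receptors, 0.23 for CREB, 0.02 for eosinophil, 0.17 for NADPH oxidase and 0.05 for oxidative phosphorylation genes, and Itgam was at 0.16. With quantile normalization, with or without the block, they were 0.03 for CREB, 0.28 for eosinophil and 0.14 for NADPH oxidase genes, and S100a9, with no sign left, was at 0. CREB genes were at 0.05 without _x_at and _s_at probe sets. Erythroid markers were at -0.26 with the filter at the 60th percentile and -0.07 with the floor, and Lamp2 was at 0.02 with the median of probe sets. Leaving out 1 array turned the sign of some medians, which then ran from -0.10 to 0.04 for CREB genes, from -0.34 to 0 for erythroid, from -0.10 to 0.28 for B cell and from -0.52 to 0.09 for eosinophil markers. They ran from -1.03 to 0.18 for interferon-stimulated genes and from -0.05 to 0.40 for mature neutrophil genes, and Itgam from -0.33 to 0.18. Of the other list values 436 kept direction and side, 43 became called and 4 lost the call. For the 96 genes these were 1366 (2 of them S100a9 at 0), 2 and 257, and 87 lost the call without moderation, 87 with the floor and 35 without the intensity trend. Arrays have no depth, and dim genes near the low end of an array are limited by its background.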

Other observations

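Within groups, the median of the macrophage list was 1.17 higher in neutrophils replicate 2 than in replicate 1, against 0.26 for all genes and -0.02 for the mast cell list. In G-MDSC the cell cycle and azurophil granule lists had medians of -1.13 and -1.11 for replicate 2 minus replicate 1, against 0.02 for all genes, while the specific and gelatinase granule list stood at 0.11.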
